A study of Mus musculus with 28 samples.

How the data were processed

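Single-cell RNA was measured in 28 mouse libraries with a Chromium 3 prime v3 kit per the labels' protocols. The deposited values are UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 per the file headers, against mm10 and with Seurat 4 per the submitters' processing notes. The counts were not scaled or transformed, and every deposited barcode holds at least 500 UMIs. Whether intronic reads were counted is not stated. Gene identifiers and symbols are those of the files, with 31253 genes in every library. The 28 libraries hold 252879 barcodes and 1486032256 UMIs.

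Barcodes with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept, which removed 4539. Scrublet scores (scanpy 1.11.5) were computed per library, and the highest scores were removed at a rate of 0.8% per 1000 barcodes, 20376 barcodes in all, which left 227964 cells. Each tissue was clustered on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9, seed 1) without correction between libraries. Clusters were named from 591 markers of 33 classes, and clusters whose leading genes spoke for another class stayed without a name. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with R 4.3.3.

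Counts were summed per library and class. Genes were tested in the pair of classes per tissue with the most cells in their smallest library, with at least 20 cells in every library, by edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood) in a model of diet, surgery and drug with 4 residual degrees of freedom, adjusted after Benjamini and Hochberg at 0.05 over the genes of a class. The effect of semaglutide that differs by diet or by surgery was tested as an interaction term with 3 residual degrees of freedom. No combination has a replicate, so the residual spread mixes library differences with interactions. Standard errors are the absolute log2 fold divided by the root of F, are approximate and were left empty where F was next to 0. Levels are CPM with TMM scaling. The 39 gene lists were tested by camera (limma 3.58.1) with its preset correlation of 0.01 where at least 5 genes were tested, and again with an estimated correlation. Shares of classes with a mean of at least 0.5% were compared by an exact two-sided permutation over 70 assignments, whose smallest p is 0.0286, adjusted over the classes and the 3 factors of a tissue. Blood and liver have 1 library per condition, so values carry 95% exact Poisson or binomial intervals for counting error and no test, ratios have 10 CPM added to both levels, and the median of a list is set against 10000 random lists of like expression.

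The groups, tests, gene lists, markers, alternatives and the rule for named genes were set before the data were examined. By that rule a class and factor names up to 6 genes in each direction with the largest log2 fold among those past the threshold, with a mean of at least 20 CPM and the same direction in 4 of 4 pairs of libraries, filled up to 3 with the smallest p where fewer passed. Interactions name up to 3 per direction by smallest adjusted p, lists up to 4 members, and blood and liver 10 genes per direction and class with at least 100 UMIs. Unnamed gene models were counted and not chosen.

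The scripts were tested on simulated counts with 200 changed genes. The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, cells with at least 1000 UMIs and at most 10% mitochondrial UMIs, predicted doublets kept, a 4-level block for the other factors, an estimated correlation, edgeR on cell numbers, 1 CPM added to ratios, and each library left out. Chosen after the data were seen were the largest cluster of a class alone, CSV and CAV left out, the cluster with granule neuron RNA left out, and brain shares without granule clusters. Gene tests in smaller classes and comparisons between tissues were not analysed here.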

Results

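The series holds 28 single-cell RNA libraries from mice, made to compare tissues of healthy mice, of mice made obese by a high-fat diet, of mice with surgically induced osteoarthritis and of mice with both, each with or without semaglutide, an agonist of the GLP-1 receptor used against diabetes and obesity. Bone marrow, brain and skeletal muscle have 8 libraries each, 1 for every combination of diet, surgery and drug. Libraries are named here by a letter for the diet (C common, H high-fat), a letter for the operation (S sham, A osteoarthritis) and a letter for the injection (V saline, S semaglutide), so that CSV is the healthy control. Blood and liver have 2 libraries each, CSV and CAV. No combination has a replicate and animal numbers per library are not given. Each factor was compared with 4 libraries against 4 balanced for the others. The spread mixes library differences and interactions.

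Total UMI counts per library were 47799132 to 94690420 in bone marrow, 54629176 to 64335861 in brain, 26357433 to 50494401 in muscle, 37573381 and 43033930 in blood, and 20883853 and 31027030 in liver. After the removal of poor barcodes and predicted doublets 59922 cells were kept in bone marrow, 63619 in brain, 88061 in muscle, 10895 in blood and 5467 in liver. The median UMI count per kept cell in a library was 4034 to 10997 in bone marrow, 3521 to 6216 in brain and 1215 to 4520 in muscle. The median mitochondrial share was 0.594% to 1.77% in bone marrow, 0.174% to 0.328% in brain and 0.117% to 0.373% in muscle. Whether brain and muscle barcodes, with such low shares, are cells or nuclei was not tested. Cell classes carry the name of their markers and are written as neuron-like and so on.

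**Figure D1:**
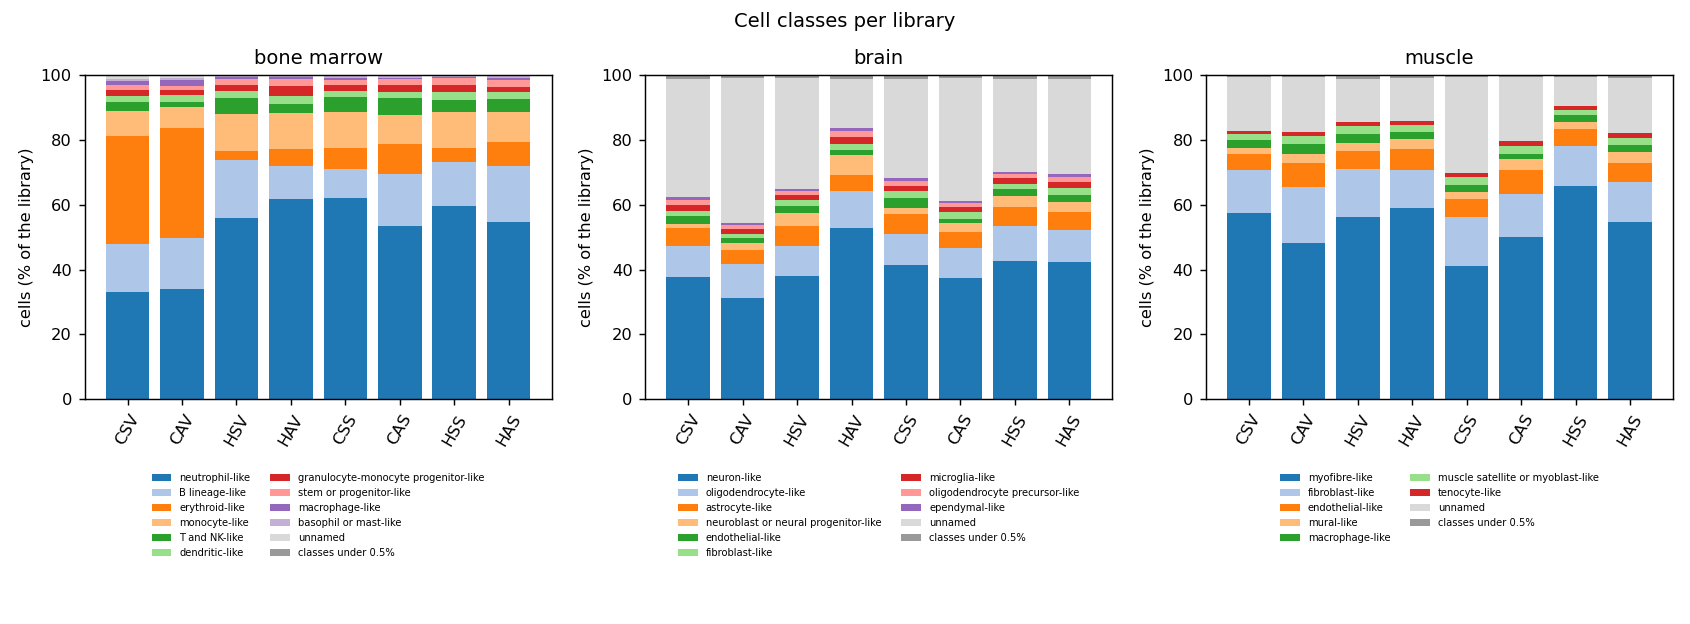
Stacked bars show the share of each named cell class (y axis, % of the cells kept) in each of the 8 libraries (x axis) of bone marrow, brain and muscle. Erythroid-like cells fill 33.2% and 33.8% of the CSV and CAV bone marrow bars and 2.79% of the lowest bar, HSV.

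Bone marrow was mostly neutrophil-like cells, with a mean of 51.9% over the 8 libraries, followed by B lineage-like (14.3%), erythroid-like (12.8%) and monocyte-like cells (9.64%). In brain, neuron-like cells took 40.5% and oligodendrocyte-like cells 9.96%, and 32.1% of cells stayed without a name, among them 16174 cells of clusters led by cerebellar granule neuron genes such as Gabra6 and Reln. Muscle held 54.0% myofibre-like, 13.8% fibroblast-like and 6.0% endothelial-like cells. In each tissue the pair of classes chosen as above was tested for genes.

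High-fat diet in bone marrow changed 21 of 10633 genes in B lineage-like cells, and 6 of the named ones encode histones, for which no list was tested. H2ac8 lay at 555 CPM ± 94.9 (SD, n = 4) on high-fat diet and 108 ± 28.6 on common diet, a log2 fold of 2.35 (SE 0.21, adjusted p = 0.00959), H1f5, a linker histone, at 1116 ± 210 and 230 ± 79.8 (2.32, SE 0.22), and H2ac4 at 136 ± 24.4 and 24.8 ± 9.90 (2.46, SE 0.23). H1f1, Hist1h2an and H3c7 rose as well, by log2 folds of 2.21 (SE 0.20), 2.31 (SE 0.33) and 2.13 (SE 0.29). These are mostly genes of replication-dependent histones, which are transcribed while DNA is copied. Rps27rt fell by 1.42 (SE 0.15) and Trim34a, a tripartite-motif gene, by 0.94 (SE 0.13), and Cyp4f18, which did not pass, had a log2 fold of -0.73 (SE 0.11, adjusted p = 0.0685). In all, 18 genes rose and 3 fell. DESeq2 called 246 genes, and edgeR called 366 without HSV and 2420 without CSV and CAV. In the largest cluster of these cells alone no gene passed in edgeR and H2ac8 had a log2 fold of -0.31. No gene passed without HAV or with a block for the 4 combinations of surgery and drug. With predicted doublets kept 2 genes passed and none of the 6 histone genes did (adjusted p = 0.0705 to 0.122). H2ac8 was lost without CSS (adjusted p = 0.0593) or HAV (0.0860), and H2ac4 without CSS (0.0593), CAV (0.0648) or HAV (0.0957). H1f5 was lost without CSS (0.0668), CAV (0.0648) or HAV (0.0860), and Hist1h2an without CSV (0.0841), CSS (0.175), HSS (0.161), CAV (0.0715) or HAV (0.188). H1f1 was lost without CAV (0.0715) or HAV (0.0957), and H3c7 without CSV (0.0778), CSS (0.136), HSS (0.124), CAV (0.0738) or HAV (0.168). Rps27rt was lost without CSV (0.0626), CSS (0.113), CAV (0.0715) or HAV (0.105), and Trim34a without CSV (0.0753), CSS (0.203), HSS (0.138), CAV (0.233), CAS (0.149), HAV (0.289) or HAS (0.106).

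Of 32 lists tested in the same B lineage-like cells 8 passed with the preset correlation, 3 up and 5 down, and 0 with an estimated correlation. All 38 tested cell cycle genes were higher on high-fat diet, with a median log2 fold of 0.94; none passed over all genes and 19 did adjusted over the list alone, and Bub1 (1.36, SE 0.37) and Mki67 (1.36, SE 0.39), which mark dividing cells, had the largest values. B lineage-like cluster 1, led by Ighd, held 89.6% of the class in CSS and 82.5% in CAS, 39.5% and 36.2% in CSV and CAV, and 31.5% to 62.3% on high-fat diet. Cluster 3, led by the precursor genes Vpreb3 and Vpreb1, held 1.35% and 2.91% in CSS and CAS, 17.0% and 17.7% in CSV and CAV, and 10.5% to 22.4% on high-fat diet. In the largest cluster alone the cell cycle and MHC class II lists missed the threshold (adjusted p = 0.241 for both), the cell cycle genes pointing downward, and the immunoglobulin list passed (0.00517). All 11 MHC class II genes were lower, with Cd74 at -0.82 (SE 0.14), and 5 of them passed adjusted over the list alone. The cell cycle and MHC class II lists had adjusted p = 9.33e-16 and 4.79e-06 with the preset correlation, and adjusted p = 0.650 with an estimated correlation for both. Immunoglobulin genes were lower in 7 of 9 cases, with Igha at -4.70 (SE 1.57), and 6 passed adjusted over the list alone (adjusted p = 0.000765, and adjusted p = 0.516 with an estimated correlation). Red cell RNA had a median log2 fold of -3.14 (adjusted p = 0.650 with an estimated correlation). The erythroid-like share was 33.2% and 33.8% in CSV and CAV and 6.32% and 9.22% in CSS and CAS. On high-fat diet it was 4.88% ± 1.95 (SD, n = 4, exact permutation p = 0.0571 for diet).

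In neutrophil-like cells no gene passed for diet in edgeR, 1983 of 11595 genes had an unadjusted p under 0.05, and DESeq2 called 206. Without HAS 13 genes passed, and 10 without CSS. The leading genes were Stfa2l1 and Cstdc4, inhibitors of cysteine proteases, at -0.81 (SE 0.10, adjusted p = 0.0705) and -0.74 (SE 0.12, adjusted p = 0.219), Gpd1l at -0.56 (SE 0.10), Csrnp1 at 0.65 (SE 0.12), Cwc25 at 0.56 (SE 0.08) and Fbxo34 at 0.46 (SE 0.09). Mitochondrially encoded genes were higher in 12 of 13 cases, led by mt-Nd5 (0.69, SE 0.26), and 5 passed adjusted over the list alone. Granule protein genes such as Prtn3 (0.68, SE 0.22) were higher in 16 of 19, with 2 past the test adjusted over the list alone, and NF-kB inflammatory genes in 18 of 28, led by Cxcl2 (2.27, SE 1.21). These 3 lists had adjusted p = 2.93e-05, 0.00210 and 0.0264 with the preset correlation, and adjusted p = 0.860 with an estimated correlation. The NF-kB list was lost without CSV (adjusted p = 0.0583) or CAS (0.182). Red cell RNA there had a median log2 fold of -3.38, with 9 of 9 genes lower (adjusted p = 0.860 with an estimated correlation) and Hbb-bs highest in CSV and CAV.

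Osteoarthritis surgery left smaller differences in bone marrow. In neutrophil-like cells Pim1, a survival kinase induced by cytokines, lay at 107 CPM ± 15.8 (SD, n = 4) after surgery and 141 ± 11.6 after sham operation (-0.41, SE 0.10, adjusted p = 1.00). Rab11fip4 had a log2 fold of -0.24 (SE 0.09) and mt-Nd4 -0.27 (SE 0.10). Prdx1, a peroxide-reducing enzyme, lay at 0.33 (SE 0.12), Lactb at 0.29 (SE 0.10) and Gde1 at 0.27 (SE 0.10). In B lineage-like cells Myc, the growth regulator, had a log2 fold of -1.03 (SE 0.30, adjusted p = 1.00), C1qbp -0.44 (SE 0.12) and Bola2 -0.42 (SE 0.12), and Bmf, a promoter of apoptosis, 0.53 (SE 0.13), Slc15a2 0.71 (SE 0.18) and Fnip1 0.46 (SE 0.12). No gene passed in either class in edgeR, with 134 and 227 genes at an unadjusted p under 0.05, and DESeq2 called 0 in both. Interferon response genes were lower in 35 of 36 cases in neutrophil-like cells, led by Ifit3b (-0.81, SE 0.64), Gbp3 (-0.77, SE 0.37) and Ifit1 (-0.76, SE 0.65), and immediate early genes in 21 of 22, led by Egr1 (-0.69, SE 1.04). These lists had adjusted p = 1.49e-06 and 0.00139 with the preset correlation and adjusted p = 0.810 with an estimated correlation. The interferon list was lost without HSS (adjusted p = 0.0829), CAS (0.146) or HAV (0.686), and the immediate early list without CSS (0.798), HSV (0.591) or HAS (0.277) and in the largest cluster alone (0.626, pointing upward). In B lineage-like cells 75 of 77 ribosomal protein genes were lower (median -0.13, adjusted p = 3.98e-12, adjusted p = 0.801 in the largest cluster alone, and adjusted p = 0.840 with an estimated correlation). Immunoglobulin RNA was lower in neutrophil-like cells too, in 9 of 11 cases with a median of -0.85 (adjusted p = 0.810 with an estimated correlation, and 0.0592 without HAV with the preset one).

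In marrow semaglutide was tested over both diets, so the difference by diet below widens errors and can hide calls. No gene passed in neutrophil-like or B lineage-like cells in edgeR, with 1641 and 1463 genes at an unadjusted p under 0.05, and DESeq2 called 103 and 14. In neutrophil-like cells Kit, a receptor of immature cells and a marker of stem or progenitor cells, lay at 27.2 CPM ± 2.84 (SD, n = 4) with semaglutide and 16.7 ± 1.52 with saline (0.70, SE 0.10, adjusted p = 0.170). Ralgps1 had a log2 fold of 0.53 (SE 0.10) and Tut4 0.47 (SE 0.09). Pnp lay at -0.56 (SE 0.10), Gclm at -0.50 (SE 0.10) and Slc28a2 at -0.44 (SE 0.08). In B lineage-like cells Cirbp, a cold-inducible RNA-binding protein, lay at 271 ± 66.4 and 118 ± 26.1 (1.17, SE 0.22, adjusted p = 0.356), Tagap at 1.22 (SE 0.24), Stoml1 at 0.89 (SE 0.14), Dynll1 at -0.72 (SE 0.16), Nup62 at -0.57 (SE 0.14) and Hes1, a Notch target, at -0.56 (SE 0.13).

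Cholesterol synthesis genes were lower with semaglutide in 22 of 24 cases in neutrophil-like cells, among them Acat2 (-0.57, SE 0.22), Mvd (-0.54, SE 0.18) and Cyp51 (-0.53, SE 0.25), and 1 passed adjusted over the list alone. The list had adjusted p = 5.14e-05 with the preset correlation, 3.08e-10 without CSV and CAV, and adjusted p = 0.662 with an estimated correlation. It was lost without HAV (adjusted p = 0.425) or HAS (0.370). Interferon response genes were lower in 34 of 36 cases, led by Gbp2 (-1.33, SE 0.42), and immediate early genes higher in 20 of 22, led by Egr1 (2.21, SE 1.28), with adjusted p = 1.73e-08 and 1.36e-06 with the preset correlation, and adjusted p = 0.662 with an estimated correlation. Without CSV and CAV the interferon list had adjusted p = 0.325 and pointed upward, and the immediate early list 0.0343, still upward. Egr1 lay at 3.72 CPM in CSV and 6.89 in CAV, without TMM scaling, against 91.0 to 244 in the other 6. In B lineage-like cells all 38 cell cycle genes were lower, with Top2a at -1.23 (SE 0.43) and 33 past the test adjusted over the list alone, and all 11 MHC class II genes higher, with H2-Oa at 0.98 (SE 0.27) and 10 past it adjusted over the list alone (adjusted p = 8.70e-17 and 1.95e-08 with the preset correlation, adjusted p = 0.612 with an estimated correlation). In the largest of the B lineage-like clusters, whose weights differ as above, both lists missed the threshold, with adjusted p = 0.903 for cell cycle and 0.682 for MHC class II. Red cell RNA was lower in all 9 genes of neutrophil-like cells (median -1.66, adjusted p = 0.662 with an estimated correlation), and the list was lost without CSV (adjusted p = 0.0888) or CAS (0.0512).

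The effect of semaglutide differed between the diets for 1490 genes in neutrophil-like cells and 2827 in B lineage-like cells. Immediate early genes of the AP-1 family led in B lineage-like cells, where Junb lay at 69.2 CPM in CSV and 76.4 in CAV and between 367 and 655 in the other 6 libraries, and Fos at 5.57 and 8.37 against 124 to 235. Fosb lay at 0.398 CPM in CSV, 1.67 in CAV and 150 to 201 in the rest. Clec2d was higher in this pair, at 420 and 373 against 40.3 to 57.5, and Maz (2.46, SE 0.16) and Adgrg1 (2.80, SE 0.23), which also marks stem or progenitor cells, had positive log2 differences. In neutrophil-like cells the interferon-induced Isg15 lay at 61.2 in CSV and 40.6 in CAV against 5.75 to 20.8, with a log2 difference of 2.96 (SE 0.18), Ifi27l2a had 2.50 (SE 0.15) and Pi16, also a fibroblast marker, 1.54 (SE 0.11). The histone genes H2ac8 and H2ac4 had differences of -3.26 (SE 0.16) and -3.68 (SE 0.18), and Dnajb9, an endoplasmic reticulum chaperone, -2.10 (SE 0.14).

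**Figure D2:**
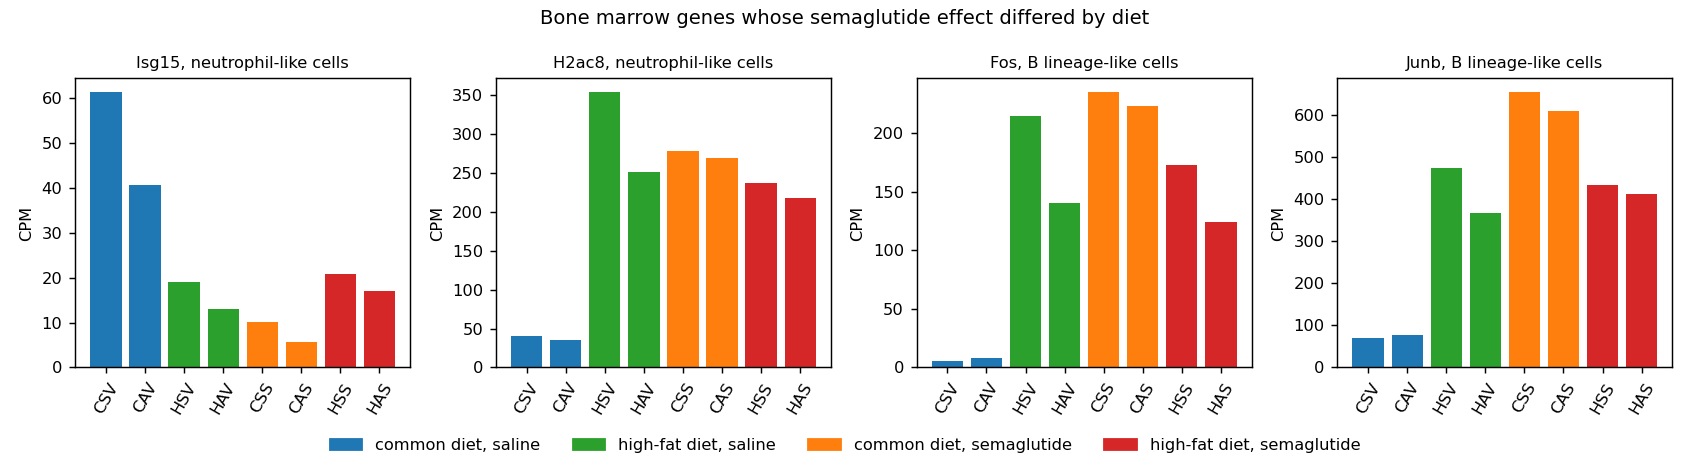
Bars show the level (y axis, CPM of the class sum) of genes with the smallest adjusted p for a semaglutide effect that differed by diet, in each of the 8 bone marrow libraries (x axis). CSV and CAV stand apart from the other 6 libraries in the genes shown.

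CSV and CAV, the marrow libraries of common diet with saline, stood apart in other measures. They held 3487 and 3519 barcodes against 7267 to 12157 in the other 6, a median of 9949 and 10997 UMIs per kept cell against 4034 to 6725, and an erythroid-like share of up to 33.8%. Hbb-bs, a globin gene, lay at 7290 and 4965 CPM without TMM scaling in their neutrophil-like cells and at 23.2 to 224 in the others. DESeq2 called 1200 and 1367 genes for the same term, and in the largest cluster of each class alone edgeR called 780 and 666. For the drug effect by surgery no gene passed in edgeR in either class, with 98 and 41 genes at an unadjusted p under 0.05, and DESeq2 called 1 and 0.

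High-fat diet in brain changed 52 of 12415 genes in oligodendrocyte-like cells, the cells that make myelin. Cox5a, a subunit of complex IV, lay at 116 CPM ± 5.66 (SD, n = 4) on high-fat diet and 67.9 ± 3.07 on common diet (0.77, SE 0.11, adjusted p = 0.00272), Ndufc1, of complex I, at 49.9 ± 4.52 and 29.5 ± 3.36 (0.76, SE 0.15), and Tmem132d, a membrane protein gene, at 268 ± 50.7 and 156 ± 22.3 (0.78, SE 0.10). Cck, a neuropeptide, rose by 0.84 (SE 0.17), Fkbp2, a protein-folding enzyme, by 0.76 (SE 0.16) and Hbb-bs, an erythroid marker, by 1.67 (SE 0.22). Gabrr2, a subunit of GABA receptors, fell by 1.22 (SE 0.19), Aim2, a sensor of DNA in the cytosol, by 0.67 (SE 0.12), Garnl3 by 0.59 (SE 0.12), Arhgap24 by 0.58 (SE 0.13) and Nrbp2 by 0.52 (SE 0.10). In all 46 genes rose and 6 fell, and DESeq2 called 44. The count was 5 without HSS and 158 without HSV. Tmem132d, Cox5a and Gabrr2 passed whichever library was left out. Hbb-bs was lost without HSS (adjusted p = 0.0549). Cck was lost without CSV (adjusted p = 0.0607), CSS (0.109), HSS (0.170), CAV (0.0911), CAS (0.0552) or HAV (0.150), and Fkbp2 without CSV (0.0883), CSS (0.0829), HSS (0.106), CAV (0.179), CAS (0.0680) or HAV (0.212). Ndufc1 was lost without CSS (0.0768), HSS (0.0804), CAV (0.119), CAS (0.0680) or HAV (0.0942), and Aim2 without CSS (0.0768), HSS (0.0932), CAV (0.0886) or HAV (0.107). Garnl3 was lost without CSV (0.0551), CSS (0.0768), HSS (0.137), CAV (0.127), CAS (0.0534) or HAV (0.199), and Arhgap24 without CSS (0.143), HSS (0.106), CAV (0.188), CAS (0.0849), HAV (0.189) or HAS (0.124). Nrbp2 was lost without CSS (0.137), HSS (0.157), CAV (0.0743), CAS (0.0660) or HAV (0.151).

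Lists of genes pointed upward in these cells and did not pass with an estimated correlation. All 77 ribosomal protein genes were higher, 14 rose over all genes tested and 70 adjusted over the list alone, with Rps29 at 0.73 (SE 0.12) and Rps15a at 0.71 (SE 0.13). Of 69 oxidative phosphorylation genes 67 were higher, 7 rose and 50 passed adjusted over the list alone. Of 15 heat shock genes 13 were higher and 3 rose, Cacybp (0.71, SE 0.15), Hsph1 (0.58, SE 0.12) and Hspa8 (0.55, SE 0.11), with 7 past the test adjusted over the list alone. The adjusted p of these lists was 5.21e-57, 8.44e-34 and 3.35e-08 with the preset correlation, and adjusted p = 0.262, 0.262 and 0.465 with an estimated correlation. Red cell RNA was higher in 7 of 7 genes, 4 of which rose over all genes and adjusted over the list alone (adjusted p = 0.262 with an estimated correlation). With a block for the 4 combinations of surgery and drug 8 genes passed, and without the 1 cluster with the most granule neuron RNA 28 did, 26 of them among the 52, with Ndufc1, Cck and Fkbp2 lost. Choroid plexus and neuronal RNA was higher in 7 of 10 genes, led by Nrgn (0.53, SE 0.12, list adjusted p = 0.0464, and adjusted p = 0.762 with an estimated correlation), and was lost in 5 of the 8 fits that left out 1 library.

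In neuron-like cells the only genes past the test for diet were 3 globin genes, below the level set for named genes and chosen after their values were seen. Hbb-bt rose by a log2 fold of 1.78 (SE 0.23), Hbb-bs by 1.51 (SE 0.15) and Hba-a2 by 1.45 (SE 0.17). Fgf1, a growth factor, had a log2 fold of 0.60 (SE 0.09, adjusted p = 0.0948), Arhgap26 0.38 (SE 0.07), Zfp692 0.38 (SE 0.07), Peg3, an imprinted gene and satellite cell marker, -0.43 (SE 0.07), Tspoap1 -0.40 (SE 0.07) and Ipo9 -0.38 (SE 0.07). All 77 ribosomal protein genes (median 0.27) and 64 of 69 oxidative phosphorylation genes (median 0.22) were higher, and all 13 mitochondrially encoded genes lower (median -0.28), with none past the test over all genes or adjusted over the list alone. Their adjusted p was 1.03e-23, 9.37e-13 and 2.47e-05 with the preset correlation, and adjusted p = 0.968 with an estimated correlation. Red cell RNA, with 3 of 8 genes risen and 4 adjusted over the list alone, had adjusted p = 0.265 with an estimated correlation. DESeq2 called 107 genes, and edgeR called 131 without CAV.

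Osteoarthritis surgery changed 137 of 12415 genes in oligodendrocyte-like cells, with 21 up and 116 down. Cmss1 (ENSMUSG00000022748), an abundant transcript here, lay at 3908 CPM ± 494 (SD, n = 4) after surgery and 2214 ± 177 after sham operation (0.82, SE 0.13, adjusted p = 0.00618). Sema3c, a secreted guidance cue, rose by 1.28 (SE 0.24), Gpd1, which links glycolysis to lipid synthesis, by 0.97 (SE 0.23), Lysmd3 by 0.92 (SE 0.21), Cyp3a13, a cytochrome P450, by 0.89 (SE 0.20) and Psat1, of serine synthesis, by 0.79 (SE 0.15). Plcxd3 fell from 126 ± 25.5 to 56.3 ± 10.7 (-1.15, SE 0.13, adjusted p = 0.000201), Kcnk10, a potassium leak channel, by 1.10 (SE 0.20), Ablim3, an actin-binding protein, by 1.13 (SE 0.16), Lrrc3b by 1.14 (SE 0.19), Trim62 by 1.12 (SE 0.21) and Wscd2 by 1.09 (SE 0.15). Plcxd3, Ablim3 and Wscd2 passed whichever library was left out. Cmss1 was lost without CSS (adjusted p = 0.0529), and Sema3c without CSV (0.160), CSS (0.0523) or HSV (0.175). Gpd1 was lost without CSV (0.286), CSS (0.149), HSV (0.137), HSS (0.0786), CAV (0.211) or HAS (0.147), and Lysmd3 without CSV (0.169), CSS (0.127), HSV (0.0953), HSS (0.120), CAV (0.213) or HAS (0.132). Cyp3a13 was lost without CSV (0.163), CSS (0.149), HSV (0.0716), CAV (0.176) or HAS (0.0514), and Psat1 without CSV (0.113) or CAV (0.0762). Lrrc3b was lost without CSV (0.0632), and Trim62 without CSV (0.113), CSS (0.0737) or CAV (0.0762). Kcnk10 was lost without CSV (0.127), CSS (0.0860), HSV (0.0953) or CAV (0.143). DESeq2 called 126 genes. The count was 13 without CSV, 239 without HAS and 24 in the largest cluster alone.

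Genes of cerebellar granule neurons moved with these calls, and the labels do not give the brain regions taken. Of the 116 genes that fell, 102 lay more than 2 times higher in the largest granule cluster than in the oligodendrocyte-like class. The 40 most abundant granule genes took 1.85% ± 0.345 (SD, n = 4) of the class's UMIs after surgery and 2.92% ± 0.705 after sham operation (exact permutation p = 0.0571). Without the cluster that held the most of their RNA, a selection made after these values were seen, 8 genes passed, all among the 137. There the 21 genes that rose had a median log2 fold of 0.72, against 0.73 in the class, and those that fell -0.34 against -0.76. Cmss1 (0.72, SE 0.11), Cdk8 (0.68, SE 0.10), Zfp365 (0.69, SE 0.13), Camk1d (0.52, SE 0.10) and D1Ertd622e (0.60, SE 0.12) were higher. Gab1 (-0.60, SE 0.10) and the unnamed gene models Gm32633 (-0.90, SE 0.16) and 2610035D17Rik (-0.66, SE 0.11) were lower.

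**Figure D3:**
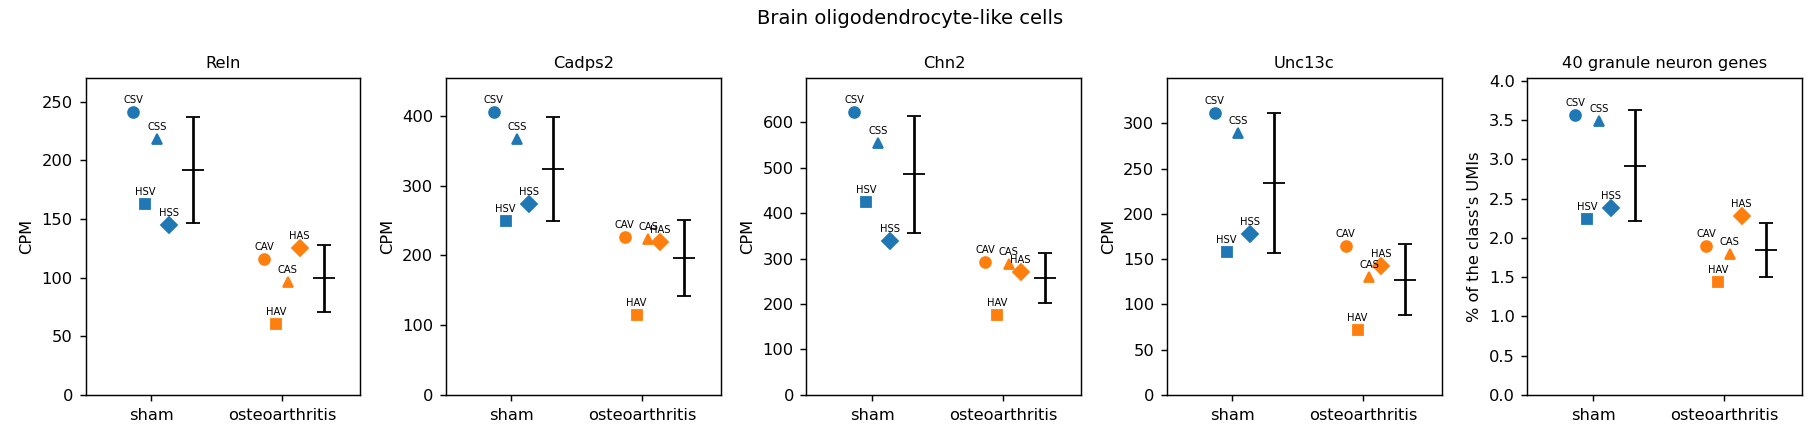
Points show levels in oligodendrocyte-like cells of the 4 sham-operated and 4 osteoarthritis brain libraries, with bars for the mean and SD. Reln (y axis, CPM) lies between 145 and 241 after sham operation and between 60.8 and 125 after surgery. Cadps2, Chn2, Unc13c and the granule gene share of UMIs (%) are lower on average after surgery.

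Glucocorticoid target genes were higher after surgery in 14 of 16 cases in oligodendrocyte-like cells, with Errfi1 at 1.34 (SE 0.65), Cdkn1a at 1.02 (SE 0.68) and Cebpd at 1.01 (SE 0.35), and 1 passed adjusted over the list alone (adjusted p = 0.000122, 0.0592 without CSV, and adjusted p = 0.874 with an estimated correlation). In neuron-like cells Cmss1 was the only gene past the test, at 1113 CPM ± 161 and 702 ± 60.4 (0.66, SE 0.08, adjusted p = 0.0454). It missed the threshold with RLE size factors (adjusted p = 0.0566), in the stricter cell selection (0.0826) and in 5 of the 8 fits that left out 1 library. There it had no call without CSS (adjusted p = 0.186), HSV (0.170), HSS (0.0646), HAV (0.197) or HAS (0.260). Srsf10 and Ptbp2, which regulate splicing, had log2 folds of 0.47 (SE 0.07, adjusted p = 0.137) and 0.38 (SE 0.07), and Etv5, a transcription factor downstream of growth factors, -0.92 (SE 0.13), Nuak1 -0.51 (SE 0.07) and Rtn4rl1, a Nogo receptor homologue, -0.47 (SE 0.08). DESeq2 called 117 genes, and edgeR called 173 without CAS.

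Blood-brain barrier genes were lower in neuron-like cells after surgery in 22 of 24 cases, among them Slco1a4 (-0.94, SE 0.20), Cdh5 (-0.94, SE 0.32) and Cldn5 (-0.58, SE 0.33), and 4 fell and 1 rose adjusted over the list alone (adjusted p = 3.09e-05, 0.0877 in the largest cluster alone, and adjusted p = 0.749 with an estimated correlation). Myelin genes were lower in 9 of 10, led by Mobp (-0.51, SE 0.25, list adjusted p = 0.0132, and adjusted p = 0.951 with an estimated correlation), and the list was lost without CSS (adjusted p = 0.870) or CAS (0.960) and in the largest cluster alone (0.892). These are markers of other cells. Red cell RNA was higher in 6 of 8 genes (median 0.43, adjusted p = 0.0215, and adjusted p = 0.749 with an estimated correlation) and lost without CAS (0.115) or HAV (0.0850). The endothelial-like share of the brain libraries was 1.6% ± 0.333 (SD, n = 4) after surgery and 2.56% ± 0.456 after sham operation, while the oligodendrocyte-like share, at 10.2% ± 0.900 and 9.71% ± 0.701, did not run with the lower myelin genes.

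Semaglutide moved no gene past the test in neuron-like or oligodendrocyte-like cells in edgeR, with 489 and 298 genes at an unadjusted p under 0.05, and DESeq2 called 1 and 0. In oligodendrocyte-like cells Fbn2, a fibrillin, had a log2 fold of -0.59 (SE 0.14, adjusted p = 1.00), Nxf1, of RNA export, -0.44 (SE 0.14), Ahctf1 -0.38 (SE 0.12), Rbm3, a cold-inducible protein, 0.45 (SE 0.13), Garnl3 0.41 (SE 0.12) and Hbb-bs 0.85 (SE 0.21). In neuron-like cells Ptgds, also an oligodendrocyte marker, had 0.57 (SE 0.16, adjusted p = 1.00), Phf6 0.27 (SE 0.10), Fkbp3 0.21 (SE 0.08), Dalrd3 -0.32 (SE 0.09), Zfp692 -0.24 (SE 0.07) and Smpd4 -0.29 (SE 0.09). All 77 ribosomal protein genes (median 0.27), 67 of 69 oxidative phosphorylation genes (median 0.21) and all 10 myelin genes (median 0.35) were higher in neuron-like cells, each with none past the test adjusted over the list alone (adjusted p = 1.23e-24, 2.62e-18 and 6.50e-06, and adjusted p = 0.675 with an estimated correlation). The myelin list was lost without CSS (adjusted p = 0.233). Red cell RNA was higher in 7 of 8 genes there (adjusted p = 0.275 with an estimated correlation) and in 6 of 7 in oligodendrocyte-like cells (adjusted p = 0.85 likewise). In oligodendrocyte-like cells all 9 adipogenic genes were higher, with Ebf2 at 1.33 (SE 0.38), and 2 passed adjusted over the list alone (adjusted p = 0.000428, and adjusted p = 0.85 with an estimated correlation).

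Among simulated genes with a 2-fold semaglutide effect, edgeR called 100% in neuron-like, 98.5% in oligodendrocyte-like, 94.0% in neutrophil-like, 82.1% in B lineage-like, 65.7% in myofibre-like and 79.1% in fibroblast-like cells. No brain gene passed in edgeR for a semaglutide effect that differed by diet or by surgery. An unadjusted p under 0.05 was found for 745 and 1219 genes in neuron-like and 371 and 639 in oligodendrocyte-like cells. DESeq2 called 2 and 2, and 0 and 0. For a simulated 2-fold drug effect by diet edgeR called 77.6% and 43.3% in these classes. Many simulated genes changed at once, so the real tests can miss more.

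High-fat diet in muscle changed 6 of 15501 genes in myofibre-like cells. Gdap1 (ENSMUSG00000025777), which acts in mitochondrial fission, lay at 151 CPM ± 28.1 (SD, n = 4) on high-fat diet and 53.0 ± 5.79 on common diet (1.5, SE 0.17, adjusted p = 0.0169), and Pde10a, a phosphodiesterase of cyclic nucleotides, at 114 ± 76.4 and 25.4 ± 10.9 (2.15, SE 0.25, adjusted p = 0.0169). Il6ra, the interleukin-6 receptor, fell by 1.67 (SE 0.23) and Zfp46 by 1.35 (SE 0.20). Chst11, of chondroitin sulfate synthesis, and Fat3, a cadherin, also rose, by 1.76 (SE 0.25) and 1.77 (SE 0.26), and lay under 20 CPM, chosen after their values were seen to complete the count. Slc4a10, an ion transporter, at 1.21 (SE 0.20, adjusted p = 0.0658), and Zcchc24 at -1.06 (SE 0.17, adjusted p = 0.0594) did not pass. Gdap1 was lost without CAV (adjusted p = 0.110), HAV (0.0756) or HAS (0.0548), and Pde10a without CAV (0.144), CAS (0.0707) or HAS (0.108). Il6ra was lost without CSS (0.0859), CAV (0.185), HAV (0.0994) or HAS (0.300), and Zfp46 without CSV (0.0553), CSS (0.103), CAV (0.210), CAS (0.0821), HAV (0.112) or HAS (0.300). With the block for surgery and drug no gene passed. DESeq2 called 194 genes, and edgeR called 56 without HSV, 42 without HSS and 20 in the largest cluster alone. Myofibre-like clusters differed in weight between libraries, with cluster 2, led by mt-Nd1, at 2.32% of the class in CSS and 46.2% in HSS, and cluster 3 at 60.1% and 6.12%.

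Extracellular matrix genes were higher in myofibre-like cells on high-fat diet in 31 of 37 cases, with Postn at 1.56 (SE 0.59) and Col3a1 at 1.35 (SE 0.40), and none passed adjusted over the list alone (adjusted p = 9.28e-05, and adjusted p = 0.892 with an estimated correlation). Adipogenic genes were higher in 13 of 16, led by the fat cell genes Adipoq (1.54, SE 0.79) and Plin1 (1.39, SE 0.59), with 1 past the test adjusted over the list alone, and interferon response genes in 21 of 25, led by Ifi27l2a (1.76, SE 0.46). Antioxidant genes were lower in 15 of 23, with Gclm at -1.15 (SE 0.24) and 2 adjusted over the list alone. These 3 lists had adjusted p = 0.0132, 0.00613 and 0.00330 with the preset correlation, and adjusted p = 0.734 with an estimated correlation. The adipogenic list was lost without CAS (adjusted p = 0.0852) and the interferon list without CSS (0.0530). Red cell RNA (6 of 8 genes, median 0.97) and choroid plexus and neuronal RNA (4 of 5, 0.65) were higher beside them, with adjusted p = 0.0291 and 0.0496 with the preset correlation and adjusted p = 0.734 with an estimated correlation, and were lost in 5 and 6 of the 8 fits that left out 1 library. Muscle held 21 neuron-like cells in HSV, 2 in HAS and 0 in the rest. Matrix and fat cell genes are made by other cells, and adipocyte-like cells, a class looked at after the data were seen, took 0.486% ± 0.0634 of cells on high-fat diet and 0.206% ± 0.0483 on common diet.

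In fibroblast-like cells Nmrk2, a kinase of NAD synthesis found in muscle, and Slc9a2, a sodium-proton exchanger, rose on high-fat diet by 2.19 (SE 0.31) and 1.96 (SE 0.28, adjusted p = 0.0363 for both). Both lay under 20 CPM and were chosen after their values were seen. Kcnma1, a potassium channel, lay at 1295 CPM ± 203 and 525 ± 159 (1.33, SE 0.25, adjusted p = 0.0791), Avil at 1.43 (SE 0.24), Fabp3, a fatty acid carrier, at 1.26 (SE 0.22), Aox3 at -1.53 (SE 0.27), Efcab5 at -1.15 (SE 0.22) and Col4a4, of basement membranes, at -0.89 (SE 0.17). Oxidative phosphorylation genes were higher in 66 of 69 cases (median 0.33), and all 11 myogenic genes, markers of myofibres, were higher too (median 0.44), with Mb, myoglobin, at 0.88 (SE 0.19) and 1 past the test adjusted over the list alone (adjusted p = 4.56e-12 and 0.000411, the latter 0.0662 in the largest cluster alone, and adjusted p = 0.941 with an estimated correlation). Of 14 cAMP-CREB targets 13 were higher, with Nr4a2 at 1.67 (SE 0.46) and 4 adjusted over the list alone (adjusted p = 2.51e-05, and adjusted p = 0.932 with an estimated correlation). DESeq2 called 113 genes, and edgeR called 120 without CSV and 0 without HSS, with a block for surgery and drug or in the largest cluster alone.

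Osteoarthritis surgery moved no gene past the test in myofibre-like or fibroblast-like cells in edgeR, with 1292 and 793 genes at an unadjusted p under 0.05, and DESeq2 called 121 and 33. With a block for the 4 combinations of diet and drug 26 and 13 genes passed, and 26 without HSS in myofibre-like and 11 without CSS in fibroblast-like cells. In fibroblast-like cells Fbxo32, the ubiquitin ligase atrogin-1 of muscle wasting, lay at 385 CPM ± 64.9 (SD, n = 4) and 150 ± 51.0 (1.37, SE 0.20, adjusted p = 0.0605). Slc7a8, an amino acid transporter, had a log2 fold of 1.12 (SE 0.16). Cd44, a hyaluronan receptor, lay at 27.7 ± 3.70 and 59.3 ± 7.77 (-1.11, SE 0.18, adjusted p = 0.0972), Ptgfrn at -0.98 (SE 0.17) and Aldh1a2, of retinoic acid synthesis, at -0.97 (SE 0.18). In myofibre-like cells Tango2 had a log2 fold of 1.32 (SE 0.22), Il6ra 1.39 (SE 0.23), Hectd2os -1.98 (SE 0.26, adjusted p = 0.0743), Ankrd23 -1.40 (SE 0.24) and Taco1, of mitochondrial translation, -1.81 (SE 0.31).

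Matrix genes were lower after surgery in both classes, and the list did not pass with an estimated correlation. In myofibre-like cells 36 of 37 were lower (median -0.86), with Timp1 at -2.71 (SE 0.73), Lum at -1.48 (SE 0.36) and Postn at -1.46 (SE 0.57), and 5 passed adjusted over the list alone. In fibroblast-like cells 27 of 34 were lower (median -0.44), with Tnc at -2.46 (SE 0.76), Postn at -1.78 (SE 0.37) and Cilp at -1.37 (SE 0.35), and 11 passed adjusted over the list alone. The list had adjusted p = 7.96e-15 and 8.84e-09 with the preset correlation, and adjusted p = 0.759 and 0.735 with an estimated correlation. Fatty acid oxidation and PPAR target genes were higher in 28 of 31 and 24 of 28 cases, with Ucp3 at 1.22 (SE 0.27) and 1.30 (SE 0.40) and Pdk4, which spares glucose, at 1.20 (SE 0.33) and 1.28 (SE 0.45), and 10 and 0 passed adjusted over the list alone (adjusted p = 6.39e-12 and 2.22e-05, and adjusted p = 0.759 and 0.735 with an estimated correlation). Markers of myofibres were higher in fibroblast-like cells beside these lists, in 9 of 11 cases with a median of 0.45 (adjusted p = 0.735 with an estimated correlation), as was red cell RNA in 5 of 5 (median 0.76, adjusted p = 0.735 likewise), and all 7 MHC class II genes, made by immune cells, were lower in myofibre-like cells (median -0.77, adjusted p = 0.759 with an estimated correlation). In fibroblast-like cells the fatty acid and myofibre marker lists were lost without CSS (adjusted p = 0.0883 and 0.0744), and in myofibre-like cells MHC class II without CSV (0.144) or CAS (0.125).

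Arntl (ENSMUSG00000055116), the clock activator also known as Bmal1, was lower in the semaglutide libraries in fibroblast-like cells of muscle, whose hours of collection are not given. It lay at 14 CPM ± 3.27 (SD, n = 4) with semaglutide and 46.7 ± 8.46 with saline, a log2 fold of -1.74 (SE 0.21, adjusted p = 0.0108), lower in 4 of 4 pairs of libraries, and was the only one of 11824 genes past the test. Its partner Npas2 lay at 28.4 ± 11.4 and 56.6 ± 21.4 (-1.01, SE 0.20, adjusted p = 0.682), and the clock output genes Hlf (0.85, SE 0.16, adjusted p = 0.522), Per3 (0.90, SE 0.20) and Dbp (1.03, SE 0.24) lay the other way without passing. The myofibre marker Mb had a log2 fold of -0.91 (SE 0.19). Arntl was lost without CSV (adjusted p = 0.0541), HSV (0.0992), HSS (0.112), CAV (0.173) or HAS (0.0643) and in the largest fibroblast-like cluster alone (0.0878). DESeq2 called 2 genes. In myofibre-like cells no gene passed in edgeR, 361 had an unadjusted p under 0.05 and DESeq2 called 0. The leading genes were Ccdc141 (0.95, SE 0.21, adjusted p = 1.00), Txnip, which curbs glucose uptake (0.73, SE 0.19), Aebp1 (0.78, SE 0.21), the calcium channel Ryr3 (-1.19, SE 0.24), Galnt17 (-0.94, SE 0.20) and Sms, of spermine synthesis (-0.65, SE 0.16).

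**Figure D4:**
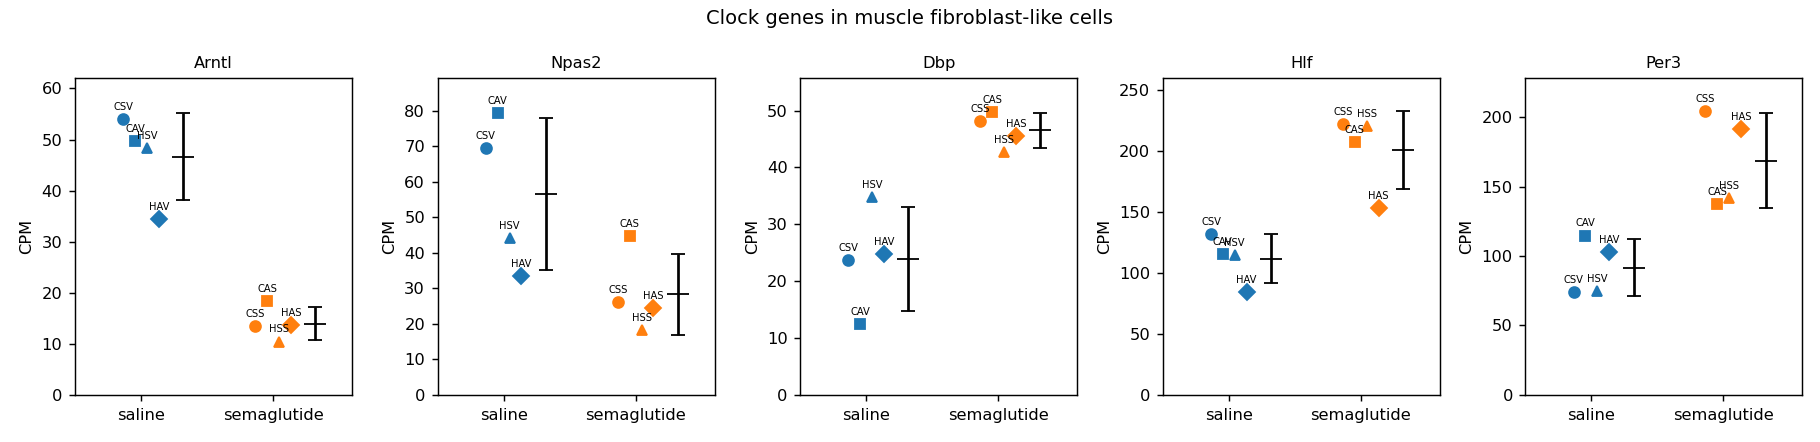
Points show levels (y axis, CPM) of clock genes in muscle fibroblast-like cells of the 4 saline and 4 semaglutide libraries, with bars for the mean and SD. Arntl lies between 34.5 and 54.1 with saline and between 10.5 and 18.4 with semaglutide, and Dbp and Per3 are higher on average with semaglutide.

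Ribosomal protein genes were higher with semaglutide in 76 of 77 cases in myofibre-like cells (median 0.19) and 56 of 76 in fibroblast-like cells (median 0.11), with none past the test adjusted over the list alone (adjusted p = 3.91e-10 and 0.00555, and adjusted p = 0.937 and 0.915 with an estimated correlation). The list was lost without HSV (adjusted p = 0.0808) or HAS (0.0576) in myofibre-like cells, and without CSS (0.0676), HSV (0.414), CAV (0.840) or HAS (0.201) in fibroblast-like cells. Matrix genes were lower in 31 of 37 cases in myofibre-like cells, with Fbn1 at -0.80 (SE 0.48), and none adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.937 with an estimated correlation), and the list was lost without CSV (0.942), CSS (0.934), CAV (0.953) or CAS (0.725). Red cell RNA was higher in 7 of 8 (median 0.28, adjusted p = 0.937 with an estimated correlation). The effect of semaglutide differed by diet for 5 of 15501 genes in myofibre-like cells, with 3 positive and 2 negative differences. All 3 positive ones are known fibroblast genes, Fndc1 (2.84, SE 0.43, adjusted p = 0.0459), the protease Fap (2.40, SE 0.38) and the fibrillin Fbn1 (2.64, SE 0.42). Fap lay at 34.7 and 23.4 CPM in CSV and CAV, 13.3 and 12.1 in CSS and CAS, 19.8 and 18.7 in HSV and HAV and 59.4 and 34.3 in HSS and HAS. Fndc1 was lost without CSV (0.138), CSS (0.0584), HSV (0.0610) or HSS (0.105), and Fap without CSV (0.197), CSS (0.0720), HSV (0.103), HSS (0.180) or CAV (0.187). Fbn1 was lost without CSV (0.138), CSS (0.0720), HSV (0.0610), HSS (0.159), CAV (0.187) or HAV (0.0508). In the stricter cells and with doublets kept 1 gene passed each, and Fndc1, Fap and Fbn1 did not (adjusted p = 0.051 to 0.10). None of the 5 passed in the largest myofibre-like cluster alone, and DESeq2 called 171 genes, while edgeR called 715 without CAS and 0 without HSS. For the other 3 muscle terms no gene passed in edgeR, with 942 genes at an unadjusted p under 0.05 by surgery in myofibre-like cells and 934 and 505 by diet and surgery in fibroblast-like cells, and DESeq2 called 0 each.

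Some cell classes held a larger or smaller share of a tissue in all 4 libraries of a level. Stem or progenitor-like cells took 2.11% ± 0.200 (SD, n = 4) of bone marrow on high-fat diet and 1.44% ± 0.297 on common diet. The lowest were CSV and CAV (1.28% and 1.13%), which held 33.2% and 33.8% erythroid-like cells, so the 2 shares were not separated. In brain, neuroblast or neural progenitor-like cells took 4.13% ± 1.32 on high-fat diet and 1.92% ± 0.719 on common diet, and astrocyte-like cells 4.91% ± 0.423 after surgery and 5.97% ± 0.307 after sham operation. In muscle, endothelial-like cells took 6.76% ± 0.682 after surgery and 5.24% ± 0.262 after sham operation, and mural-like cells, the support cells of vessels, 3.17% ± 0.173 and 2.18% ± 0.212. These 5 shares and the brain endothelial-like share each had an exact permutation p of 0.0286 (two-sided), the smallest that 70 assignments allow, and none held after correction, with adjusted p = 0.571 in bone marrow, 0.257 in brain and 0.300 in muscle. In edgeR on cell numbers 1 class passed, the neuroblast or neural progenitor-like one (adjusted p = 0.0327). Granule clusters took 9.20% (HAV) to 38.7% (CAV) of the brain libraries, whose regions are not given, and among the other cells, a test chosen after the data were seen, the neuroblast levels overlapped (exact permutation p = 0.0571, edgeR adjusted p = 0.0536), while the astrocyte-like and endothelial-like levels did not (exact permutation p = 0.0286). No class separated by semaglutide in this way.

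**Figure D5:**
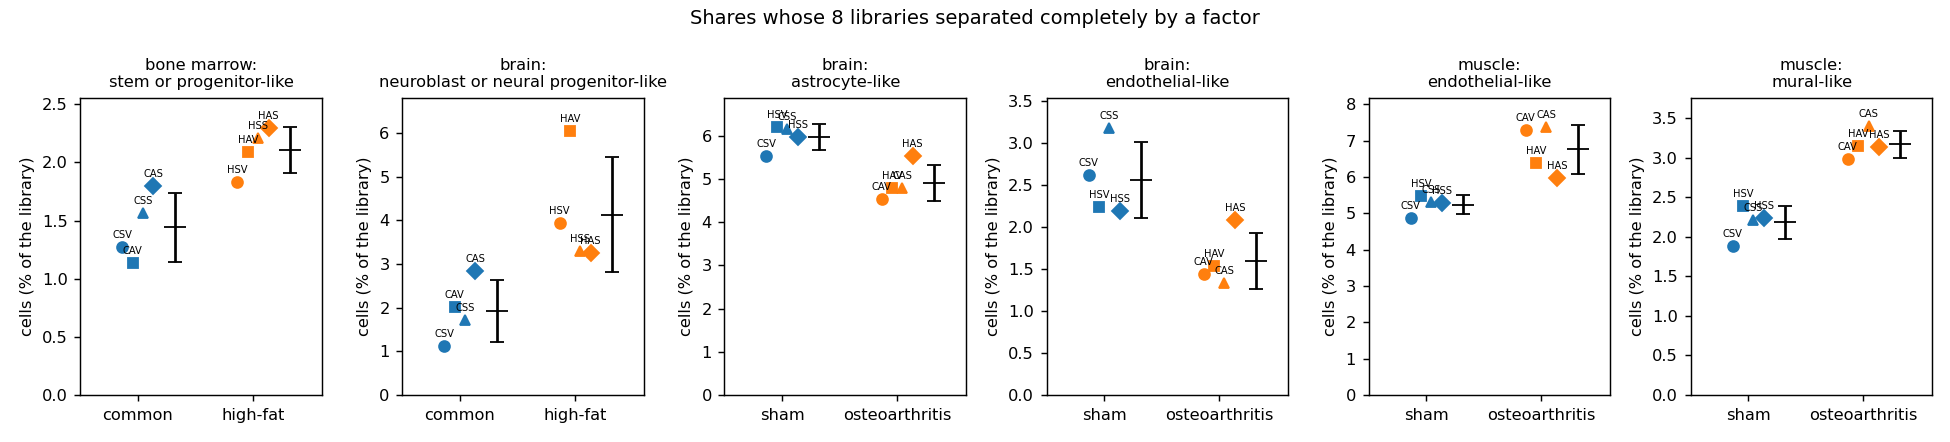
Points show the share of a class (y axis, % of the cells kept) in the 4 libraries of each level of a factor (x axis), with bars for the mean and SD, for the 6 shares whose levels did not overlap. Mural-like cells in muscle lie at 3.17% on average after surgery and 2.18% after sham operation.

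In blood the osteoarthritis and sham libraries of common diet and saline were compared as values, with 1 library each and no test. Intervals are 95% and cover counting error alone. In T and NK-like cells Socs3, which damps cytokine signalling, lay at 211 CPM (204 to 219) in the osteoarthritis library and 92.8 (87.8 to 98.1) in the sham library, Zfp36, which destabilises inflammatory mRNA, at 232 (223 to 240) and 109 (103 to 114), and Socs1 at 125 (119 to 131) and 62.8 (58.6 to 67.1). Sbno2, Jmjd1c, Nfkbiz, Frmd4b and Gadd45g were higher too, by 1.94, 1.65, 1.6, 1.56 and 1.54 times, as were Lyz2 and Hbb-bt, markers of monocytes and red cells, by 1.66 and 1.59. Cd74, H2-Aa, H2-Eb1 and H2-Ab1, MHC class II markers of B or dendritic cells, were lower by 1.82, 1.81, 1.61 and 1.52 times. Ighd of B cells and Pf4 of platelets were 1.42 times lower, and Rpl35, Bola2, Arhgap31 and Trgc2 1.42 to 1.46 times. Interferon response genes were higher in 34 of 38 cases, with a median log2 ratio of 0.20 above that of 100% of 10000 random lists of like expression.

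In B lineage-like cells of blood the globin genes Hbb-bs, Hba-a2, Hbb-bt and Hba-a1 were 2.0, 1.59, 1.54 and 1.53 times higher in the osteoarthritis library, Lyz2 and Gzma, markers of monocytes and of T and NK cells, 1.84 and 1.72 times, and the cell cycle gene Ccnd2, Id2, Nedd4 and the chaperone Hspa8 1.68, 1.57, 1.54 and 1.53 times. Wfdc17 was 1.74 times lower, Zrsr1 1.64, Cd200, an inhibitory surface protein, 1.57, Hist1h2ap and Serpina3g 1.49 each, Smim27 1.41, and the ribosomal Rpl35, Rps28, Rpl38 and Rps21 1.48, 1.45, 1.43 and 1.41 times. Heat shock genes were higher in 15 of 17 cases (median log2 ratio 0.27, percentile 100). Monocyte-like cells took 5.83% (5.22 to 6.49, exact Clopper-Pearson) of the osteoarthritis library and 3.19% (2.74 to 3.69) of the sham library, T and NK-like cells 38.6% (37.3 to 39.9) and 35.5% (34.2 to 36.8), and B lineage-like cells 32.2% and 31.1%. Cells without a name took 17.5% and 25.4%, among them a cluster with the B cell genes Cr2, Bank1 and Ighd, so no direction is read from the B lineage-like share.

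In liver, endothelial-like cells of the osteoarthritis library had higher levels of genes of protein folding, in 1 library whose handling cannot be told apart from surgery. Manf, a stress-induced endoplasmic reticulum protein, lay at 323 CPM (311 to 335) and 136 (128 to 144), Hspb1, a small heat shock protein, at 484 (470 to 499) and 218 (208 to 228), and Sdf2l1, Hyou1, Creld2 and Stip1 were 2.48, 2.31, 2.16 and 2.14 times higher. Of 24 genes of the unfolded protein response 23 were higher (median log2 ratio 0.76) and of 18 heat shock genes 18 (0.56), both at percentile 100. Immediate early genes, which handling of tissue can induce, were higher in 19 of 23 cases, and all 13 mitochondrially encoded genes lower (median -0.29). The globin genes Hbb-bs, Hba-a2, Hba-a1 and Hbb-bt were 22.6, 13.2, 13.1 and 4.65 times higher in the same cells, and with 1 CPM in place of 10 added to both levels their log2 ratios were 5.1, 4.67, 4.40 and 3.95. Lars2, a mitochondrial tRNA synthetase, was 2.16 times lower, the liver genes Car3, Mup17, Akr1c6 and Rgn 1.90, 1.83, 1.77 and 1.68 times, Lyz2 1.93 times, and Ednrb, the endothelin receptor, Nrarp, a Notch target, Ccdc152 and Inhbb 1.73, 1.68, 1.67 and 1.63 times.

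Hepatocyte-like cells of the osteoarthritis library had less serum amyloid RNA. Saa2 lay at 11 CPM (7.37 to 15.8) and 422 (402 to 442), Saa1 at 78.6 (68.2 to 90.1) and 614 (590 to 639), and Saa3 at 1.52 (0.414 to 3.89) and 30.7 (25.5 to 36.7). The complement and acute phase list as a whole pointed the other way, with 11 of 17 genes higher (median log2 ratio 0.40). Glul, glutamine synthetase of the cells around the central vein, was 2.57 times lower, its neighbour in zonation Oat 2.86, and Fitm1, Ifi27 and Csrp3 2.66, 2.61 and 2.47 times. The neutrophil markers S100a9 and S100a8 were 9.55 and 7.52 times lower. The macrophage markers C1qa, Cd5l, Clec4f, C1qc, C1qb and Fcna were 5.16, 4.98, 4.86, 4.8, 4.28 and 4.66 times higher, and Wfdc17, Spp1, H2-Ab1 and Lyz2 4.71, 4.46, 4.27 and 3.77 times. With 1 CPM in place of 10 added to both levels the log2 ratios of Fcna, Saa3 and S100a9 were 4.05, -3.65 and -4.31. Unfolded protein response genes were higher in 21 of 24 cases, heat shock genes in 14 of 18 and immediate early genes in 23 of 23. All 13 mitochondrially encoded genes were higher too (median log2 ratio 0.38, percentile 99.9), and the median mitochondrial share was 0.0705% in hepatocyte-like cluster 3 and 7.18% in cluster 20. With predicted doublets kept Lyz2 had a log2 ratio of -0.02. Cluster 3 held 72.0% of the hepatocyte-like cells of the sham library and 39.8% of those of the osteoarthritis library.

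Endothelial-like cells took 44.1% (42.0 to 46.2) of the osteoarthritis liver library and 24.3% (22.9 to 25.8) of the sham library, hepatocyte-like cells 12.6% (11.2 to 14) and 9.44% (8.47 to 10.5), B lineage-like cells 7.15% (6.09 to 8.32) and 16.3% (15.1 to 17.6), and T and NK-like cells 8.27% (7.14 to 9.52) and 16.4% (15.1 to 17.7). Glp1r, which encodes the receptor of semaglutide, had low levels in all 5 tissues. Neuron-like cells of brain had 0.818 CPM from 224 UMIs, near the level of oligodendrocyte-like (0.792), astrocyte-like (0.745) and endothelial-like cells (1.09) there, and hepatic stellate-like cells of liver 18.1 CPM from 13. Brain held 347 UMIs of it (0.777 CPM), liver 45 (0.921 CPM), muscle 26, bone marrow 19 and blood 2.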

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

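The tests of causes for the 3 patterns below were chosen once the calls were known. The predictions for red cell RNA, time of day, neuronal RNA and the mix of oligodendrocyte clusters were written before their own values were seen. Those for the batch of CSV and CAV, fibroblast clusters, granule neuron RNA and direction of the oligodendrocyte genes were written after. In bone marrow the granulocyte-monocyte progenitor-like share of HAV lay far above the other 7 libraries, at 3.19% against 1.47% to 2.13%. In brain HAS held 11601 barcodes against 6963 to 8951, and in muscle the satellite or myoblast-like share of HSS was 1.5% against 1.98% to 2.38%. With 39 such sets tested, chance alone puts about 1 in 20 this far apart, and 3 did so. The effect of semaglutide differed by diet for 1490 genes in neutrophil-like and 2827 in B lineage-like cells of bone marrow and for 5 in myofibre-like cells of muscle, by a test of the interaction.

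In the marrow drug effect by diet CSV and CAV stand out, with Fos and Junb low and Isg15 and Clec2d high in both classes. H2ac8 and H2ac4 are low there in neutrophil-like cells, where Ifi27l2a is instead lowest in CSS and CAS. How many calls rest on CSV and CAV was not tested. Red cell RNA from the erythroid-like cells of CSV and CAV was excluded as the whole cause. Of the called genes in neutrophil-like cells 5.03% (75 of 1490) had a positive difference and lay at least 4 times higher in erythroid-like cells. Of 596 genes called in both classes 94.8% (565) had the same sign, as a separate handling or library batch of CSV and CAV would give, but common diet with saline is also what this pair shares. The design confounds batch and biology for these genes, and a response to semaglutide that depends on diet may remain, as an untested hypothesis.

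The lower Arntl with higher Dbp and Per3 in muscle fibroblast-like cells resembles a shift in clock phase. Another mix of fibroblast clusters was excluded as the cause of the fold, since Arntl in the largest cluster alone had -1.66 (SE 0.261) against -1.74 (SE 0.210) in the class. Its adjusted p rose to 0.0878 there, with fewer cells and a larger error. A different time of day at collection may give the same picture: the clock score in myofibre-like cells was higher by 0.58 (SE 0.277) with semaglutide, which decides neither way, and the labels give no collection times. An effect of semaglutide on the clock is an untested hypothesis and stays as open as the hour of collection.

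The genes lower after surgery in brain oligodendrocyte-like cells may come in part from granule neuron RNA. The 40 granule genes tested had a median log2 fold of -0.62, all of them lower, while 44 general neuron genes had -0.0340, which excludes less neuronal RNA in general. In the largest cluster alone the called genes moved in their own direction by a median of 0.427, against 0.753 in the class. The mix of clusters differed between libraries. Cluster 18, with the most granule RNA, held 481 of the 1028 oligodendrocyte-like cells of HAS and 38 to 111 cells in each other library. The SE over genes (0.0244) holds no spread between libraries, so how far another mix of clusters explains the calls stays open. For genes that fell the median there was -0.35 against -0.76, so another mix may explain part of them. For genes that rose it was 0.75 against 0.73, which argues against it for these as a set. CAV and CAS held the most granule cells (38.7% and 31.9% of the library) and yet 1.89% and 1.80% granule RNA in these cells, against 3.56% and 3.49% in CSV and CSS, so that the source of this RNA stays open, as does a biological effect of surgery on the genes that rose.

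Other splits of the same 8 libraries were fitted, 33 per factor and 32 per interaction, and those that called as many genes or lists were counted. For 4 results only the real split called as many, which, uncorrected over the results, does not exclude chance. In oligodendrocyte-like cells these were diet (52 against at most 15) and surgery (137 against at most 43). The others were the drug effect by diet in bone marrow (4317 against 2) and diet in myofibre-like cells (6 against 1). Another split called as many for the other results with a count above 0. Given are the number of splits with as many calls, then the real count and the highest other. In bone marrow: lists for semaglutide 5 of 33 with 26 against 28, diet in B lineage-like 2 of 33 with 21 against 111, lists for diet 22 of 33 with 17 against 24, lists for surgery 21 of 33 with 18 against 26. In brain: lists for semaglutide 15 of 33 with 16 against 31, diet in neuron-like 3 of 33 with 3 against 6, lists for diet 19 of 33 with 16 against 34, surgery in neuron-like 3 of 33 with 1 against 40, lists for surgery 19 of 33 with 15 against 31. In muscle: semaglutide in fibroblast-like 4 of 33 with 1 against 6, lists for semaglutide 33 of 33 with 5 against 33, diet in fibroblast-like 3 of 33 with 2 against 63, lists for diet 21 of 33 with 14 against 31, lists for surgery 15 of 33 with 19 against 30, drug effect by diet 4 of 32 with 5 against 21. Where the real count was 0 every split has as many (33 of 33, or 32 of 32), so nothing is tested and the highest counts show only what other splits call. These were in bone marrow 3 and 1604 for semaglutide in neutrophil-like and B lineage-like cells, 1638 and 2431 for surgery, 6 for diet in neutrophil-like cells and 4317 for the drug effect by surgery, in brain 169 and 6 for semaglutide in neuron-like and oligodendrocyte-like cells and 22 for each interaction, and in muscle 3 and 2 for semaglutide and surgery in myofibre-like cells, 2 for surgery in fibroblast-like cells and 21 for the drug effect by surgery. The split of CSV, HSS, CAV and HAS from the rest, which is the contrast of diet by drug, called 1638 and 2431 genes in bone marrow, and that of CSV, CAV, HAV and HAS called 1604.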

How the results depend on the processing

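The tests in the largest cluster, without CSV and CAV and without granule clusters were chosen after the results were seen. No label pairs animals, so libraries matched on the other 2 factors were fitted as a 4-level block instead. Counts within 1.5 times, and blood and liver shares within their counting interval, made up 22 of 24 results with RLE size factors, 6 of 24 without a filter on low counts, 41 of 50 in the stricter cells, 45 of 50 with doublets kept, 10 of 18 with the block, 7 of 24 with DESeq2, 0 of 9 with an estimated correlation and 244 of 336 with 1 library left out. Of the 37 called genes named by the rule 36 kept their call with RLE size factors, 26 with doublets kept, 17 with the block and 35 of 36 with DESeq2. Without a filter on low counts these counts changed by more than 1.5 times: bone marrow in neutrophil-like diet 0 to 3, in B lineage-like diet 21 to 59, drug effect by surgery 0 to 1, and in brain in neuron-like diet 3 to 39, surgery 1 to 7, in oligodendrocyte-like diet 52 to 236, surgery 137 to 417, semaglutide 0 to 1, drug effect by diet 0 to 2, by surgery 0 to 7, and in muscle in myofibre-like diet 6 to 177, surgery 0 to 138, semaglutide 0 to 3, in fibroblast-like diet 2 to 330, surgery 0 to 107, semaglutide 1 to 14, drug effect by diet 5 to 428, by surgery 0 to 1. With the other 2 factors as a 4-level block: bone marrow in neutrophil-like diet 0 to 1, in B lineage-like diet 21 to 0, and in brain in neuron-like surgery 1 to 4, in oligodendrocyte-like diet 52 to 8, and in muscle in myofibre-like diet 6 to 0, surgery 0 to 26, in fibroblast-like diet 2 to 0, surgery 0 to 13. With DESeq2: bone marrow in neutrophil-like diet 0 to 206, semaglutide 0 to 103, in B lineage-like diet 21 to 246, semaglutide 0 to 14, drug effect by diet 4317 to 2567, by surgery 0 to 1, and in brain in neuron-like diet 3 to 107, surgery 1 to 117, semaglutide 0 to 1, drug effect by diet 0 to 2, by surgery 0 to 2, and in muscle in myofibre-like diet 6 to 194, surgery 0 to 121, in fibroblast-like diet 2 to 113, surgery 0 to 33, semaglutide 1 to 2, drug effect by diet 5 to 171. In the largest cluster of a class alone: bone marrow in neutrophil-like diet 0 to 4, semaglutide 0 to 1, in B lineage-like diet 21 to 0, drug effect by diet 4317 to 1446, and in brain in neuron-like diet 3 to 17, surgery 1 to 2, in oligodendrocyte-like surgery 137 to 24, lists for surgery 15 to 6, semaglutide 16 to 10, and in muscle in myofibre-like diet 6 to 20, surgery 0 to 2, in fibroblast-like diet 2 to 0, semaglutide 1 to 0, lists for surgery 19 to 8, semaglutide 5 to 3, drug effect by diet 5 to 0. With CSV and CAV left out, where the drug effect by diet has no estimate: bone marrow in neutrophil-like diet 0 to 19, surgery 0 to 1, in B lineage-like diet 21 to 2420, surgery 0 to 93, semaglutide 0 to 1, lists for semaglutide 26 to 17, drug effect by surgery 0 to 4. With predicted doublets kept: bone marrow in B lineage-like diet 21 to 2, and in brain in oligodendrocyte-like diet 52 to 91, and in muscle in fibroblast-like diet 2 to 8, surgery 0 to 7, drug effect by diet 5 to 1. With RLE size factors: brain in neuron-like surgery 1 to 0, and in muscle in myofibre-like surgery 0 to 2. In cells with at least 1000 UMIs and at most 10% mitochondrial UMIs: brain in neuron-like surgery 1 to 0, and in muscle in myofibre-like diet 6 to 32, surgery 0 to 1, lists for surgery 19 to 12, drug effect by diet 5 to 1, and in liver share of endothelial-like, sham library 24.3 to 26.2, osteoarthritis library 44.1 to 46.6, share of hepatocyte-like, sham library 9.44 to 7.74, osteoarthritis library 12.6 to 10.5. With the cluster with granule RNA left out: brain in oligodendrocyte-like diet 52 to 28, surgery 137 to 8. With an estimated correlation all these went to 0: bone marrow lists for diet 17, surgery 18, semaglutide 26, and in brain lists for diet 16, surgery 15, semaglutide 16, and in muscle lists for diet 14, surgery 19, semaglutide 5. With edgeR on cell numbers: brain cell class shares by diet 0 to 1. H2ac8 in B lineage-like cells turned to -0.31 in the largest cluster, and Lyz2 in liver hepatocyte-like cells to -0.0226 with doublets kept. With 1 library left out the lowest and highest counts were, with the library whose absence gave each: In bone marrow, in neutrophil-like diet 0 to 13 (CSV, HAS), in B lineage-like diet 0 to 366 (HAV, HSV), lists for diet 15 to 24 (CSV, HAS), surgery 14 to 23 (HAV, CSV), semaglutide 21 to 27 (CAS, HSS), drug effect by diet 2351 to 3997 (HAS, CSS), by surgery 0 to 1 (CSV, HSV). In brain, in neuron-like diet 0 to 131 (CSV, CAV), surgery 0 to 173 (CSS, CAS), semaglutide 0 to 1 (CSV, CAS), in oligodendrocyte-like diet 5 to 158 (HSS, HSV), surgery 13 to 239 (CSV, HAS), lists for diet 16 to 20 (HSS, CSS), surgery 8 to 21 (CSV, HSV), semaglutide 13 to 25 (HAS, HAV), drug effect by diet 0 to 14 (HSV, CSS), by surgery 0 to 1 (CSS, CSV). In muscle, in myofibre-like diet 0 to 56 (CAV, HSV), surgery 0 to 26 (CSV, HSS), in fibroblast-like diet 0 to 120 (HSS, CSV), surgery 0 to 11 (CSV, CSS), semaglutide 0 to 1 (CSV, CSS), lists for diet 13 to 24 (HSV, CSV), surgery 12 to 26 (CSV, CAV), semaglutide 7 to 16 (CSV, CSS), drug effect by diet 0 to 715 (HSS, CAS), by surgery 0 to 4 (CSV, HSS). The cause was not tested for any of these changes. With 1 CPM in place of 10 added to both levels 31 of 80 blood and liver ratios left their counting interval and none reversed. Of simulated genes with a 1.5-fold semaglutide effect 8.96% were called in myofibre-like and 64.2% in oligodendrocyte-like cells. Depth does not explain this, since the myofibre-like sums hold more UMIs, while their common BCV was 0.277 against 0.124.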

Other observations

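The clock score over 20 classes and the blood cluster below come from tests chosen after the results were seen. The clock score, the mean log2 level of Dbp, Tef, Hlf, Per2, Per3, Nr1d1, Nr1d2 and Ciart minus that of Arntl, Npas2, Clock and Nfil3, was higher with semaglutide in 4 of 4 pairs of libraries in 6 muscle classes. The differences were 1.49 (SE 0.197) in fibroblast-like, 1.38 (SE 0.206) in tenocyte-like, 1.31 (SE 0.226) in mural-like, 1.26 (SE 0.296) in endothelial-like, 0.908 (SE 0.152) in macrophage-like and 0.792 (SE 0.286) in satellite or myoblast-like cells. It was higher in 4 of 4 pairs outside muscle too, in brain endothelial-like (0.832, SE 0.122), fibroblast-like (0.698, SE 0.188), astrocyte-like (0.417, SE 0.137) and neuron-like cells (0.207, SE 0.0206) and in bone marrow B lineage-like (0.530, SE 0.280) and monocyte-like cells (0.370, SE 0.157). In the other 8 classes fewer pairs were higher: 3 in muscle myofibre-like (0.580, SE 0.277), brain oligodendrocyte precursor-like (0.487, SE 0.262) and oligodendrocyte-like (0.167, SE 0.115) and marrow dendritic-like cells (0.0696, SE 0.168), 2 in brain neuroblast-like (0.0944, SE 0.174) and microglia-like (0.0844, SE 0.229) and marrow erythroid-like cells (-0.0983, SE 0.181) and 1 in marrow neutrophil-like cells (0.0287, SE 0.0604). The 6 muscle classes and brain astrocyte-like cells each had the smallest exact permutation p, 0.0286 (two-sided), and none passed over 20 classes (adjusted p = 0.0816).

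Adipocyte-like cells in muscle, a class under the minimum share, had an exact permutation p of 0.0286 (two-sided) for diet and an adjusted p = 0.343. Glp1r was at 0 UMIs in 8 of 11 groups of bone marrow cells, 1 of 13 in brain, 4 of 11 in muscle, 7 of 8 in blood and 8 of 13 in liver. In blood 1200 barcodes formed a cluster without a name led by Gsto1, Psca and Plet1, with 62.8% of them from CSV.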
